A study of Mus musculus with 6 samples.

How the data were processed

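Messenger RNA from the hippocampus of 2-month-old C57BL/6 mice was sequenced in 6 samples, 3 from control mice and 3 from sATF6-KI mice, as the labels give the groups. Control mice carried Emx1-Cre, a Cre recombinase driven in the forebrain. In which hippocampal cells it acted was not examined here. The sATF6-KI mice carried the same Cre and a Rosa26 allele that encodes short-form ATF6 joined to MER. Fusions to such receptor parts are usually controlled by a ligand, and whether the mice received one is not given in the sources used here. Per the labels' protocols, tissue was snap frozen, RNA was extracted with Trizol and treated with DNase, and libraries were made with a stranded KAPA messenger RNA kit. Per the submitters' processing notes, the tools were Trim Galore, cutadapt, STAR, HTSeq and DESeq2, with no versions. The genome build, the annotation, the strand setting of the counting and the filter on low genes are not given in the sources used here.

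The authors' deposited table holds 1 comparison, sATF6-KI over control, for 17385 genes, of which 15508 are marked as protein-coding. Its columns are as follows, per the file headers. The authors' baseMean is a mean normalized expression signal over all libraries, and ran from 2.12 to 295141 with a median of 622. The authors' fold change is on the log2 scale. The authors' Wald statistic is a score with no fixed range. The deposited p-value and its false discovery rate adjusted form complete the comparison. A further 6 columns hold values per library under names that match no sample label. They were given to no sample or group and were not used in any step. The depth per sample is therefore unknown here, no value per replicate is given, and the precision of each fold change is that of the authors' test alone.

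The columns were checked against each other. The deposited p-value differed from the two-sided normal p of the Wald statistic by at most 2.89e-15, and the deposited adjusted p differed from a Benjamini-Hochberg adjustment over the listed genes by at most 3.89e-15. The deposited standard error, on the log2 scale, did not go with the Wald statistic: the fold change divided by it was at least 1.05 times the statistic, with a median of 1.21 times. For 98.4% of genes the deposited error followed from the Wald error with 1 constant prior precision, within 2% of a median of 19.7, as the error of a shrunken fold change would. The error used throughout is therefore the Wald standard error, the log2 fold change divided by the Wald statistic, with a median of 0.10 against 0.08 for the deposited error. Intervals are 95% Wald intervals from it.

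A gene was called at the authors' adjusted p under 0.05. The planned test of the counts, edgeR's quasi-likelihood test, was not run because no column of counts per labelled sample was used, and the authors' DESeq2 comparison takes its place. Gene lists, fixed before the data were examined, were tested with cameraPR of limma 3.58.1 in R 4.3.3 on the Wald statistics, with a preset inter-gene correlation of 0.01. It replaces the planned camera test, which needs values per sample. It compares the statistics of a list with those of all other genes, and its p was adjusted by Benjamini-Hochberg over the tested lists. The sex-linked genes were counted only. The lists cover ER chaperones and folding enzymes, ER-associated degradation, ER translocation and early secretory transport, N-glycosylation, the PERK-ATF4 and IRE1-XBP1 branches, cytosolic heat shock, apoptosis, antioxidant enzymes, autophagy and lysosome, cholesterol synthesis, immediate early genes, the glutamatergic synapse, and markers of glutamatergic neurons, GABAergic interneurons, astrocytes, reactive astrocytes, microglia, oligodendrocytes, endothelial and mural cells, choroid plexus, thalamus and striatum, and blood. Other work used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

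Both steps were tested on simulated data first. With Wald statistics simulated for 17385 genes from the errors of the sATF6-KI comparison and 200 genes changed, 25.5% of genes changed by 1.2-fold, 66.1% of those changed by 1.5-fold and 79.5% of those changed by 2-fold were called, and 5.1% of calls were false. The simulation took the errors as known and the genes as independent, so a false share near 0.05 follows by construction. It does not test the authors' DESeq2 fit. The real comparison called 928 genes, so the recovered shares may not carry over to it. With the same 17385 genes, 99.7% of lists were recovered when the Wald statistic of every member was shifted by 1.5. Of unshifted lists, 5.5% had p under 0.05. That share was 12.4% when genes of a list correlated at 0.05. The preset correlation thus gives p-values that are too small where genes of a list move together. Unchanged genes had independent standard normal statistics, so the share of 5.5% follows by construction. Real statistics may spread more widely and real lists may shift only in part, so the recovered share may not carry over.

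The named genes follow a rule fixed before the data were examined. They are Atf6, Esr1 and Emx1, the 10 genes with the largest log2 fold change each way among those called with a baseMean of at least 1 after scaling the summed baseMean to 1000000, and the members of each list with the smallest p, 2 per list and up to 4 for 5 of the ER and unfolded protein response lists. The planned condition that replicates of both groups do not overlap could not be applied. A gene that the rule names is not reported here. Gene names are those of the table. Of its IDs, 17166 matched the GENCODE M21 names and 219 did not. Coordinates are those of GENCODE M21 on GRCm38, which may not be the annotation the authors counted on. Of 80 named genes with coordinates, 23 overlap another listed gene, 6 of them on the same strand. Alternatives tried were other thresholds and adjustments, a minimum baseMean of 10, protein-coding genes alone, ranks of the statistics, higher inter-gene correlations and a narrower background. Values per sample, replicate blocks and fits without single replicates were not run.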

Results

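The data are one comparison of hippocampal messenger RNA between 3 sATF6-KI and 3 control mice. ATF6 is an ER membrane protein whose cytosolic part, once released, acts as a transcription factor of the unfolded protein response. The series title states the question as the effect on gene expression of short-form ATF6 in neurons. All fold changes, errors and p-values of single genes below come from the authors' deposited table, and a value after ± is the Wald standard error of a log2 fold change. No values per replicate are given.

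The transgene's parts were looked at first. Atf6 was 1.43-fold higher in sATF6-KI in the authors' deposited table (95% interval 1.31 to 1.55), a log2 fold change of 0.51 ± 0.06 with the authors' adjusted p = 1.03e-13. Atf6 lies on chromosome 1 from 170704674 to 170867771 (GRCm38). Esr1, the gene for estrogen receptor alpha, on chromosome 10 from 4611593 to 5005614 (GRCm38), was 68.0-fold higher in the authors' deposited table (95% interval 59.6 to 77.6). MER is a modified ligand-binding part of this receptor. Whether reads of the transgene were counted at Esr1 or at Atf6 was not tested, so neither rise can be assigned to the mouse gene itself. Emx1, whose Cre both groups carry, differed by -0.12 ± 0.12 on the log2 scale in the authors' deposited table, the authors' adjusted p = 0.713. Gt(ROSA)26Sor, chosen after its value was seen, had a log2 fold change of 0.54 ± 0.10 in the authors' deposited table, and Atf6b, the related ER membrane factor, also chosen so, had 0.03 ± 0.07.

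In sATF6-KI hippocampus 592 genes were higher and 336 lower than in control, out of 17385, at the authors' adjusted p under 0.05. The increases were larger: the median called gene was 1.41-fold higher among those that rose and 1.19-fold lower among those that fell. With a fold change of at least 1.5 as well, 206 genes were higher and 11 lower. The largest increase in the authors' deposited table was that of Derl3, a component of ER-associated degradation on chromosome 10 from 75893413 to 75895941 (GRCm38), at 89.9-fold (95% interval 75.7 to 107). Among called genes with a baseMean of at least 1 after scaling, Sdf2l1, an ER chaperone cofactor, came after Esr1 at 12.9-fold in the authors' deposited table. Tes, a focal adhesion protein, followed at 9.79-fold in the authors' deposited table, and Manf, a secreted ER stress protein, at 8.66-fold. Trh, the thyrotropin-releasing hormone precursor, was 8.52-fold higher in the authors' deposited table, Scarf2 8.18-fold, C1qtnf1 7.64-fold and Fkbp11, an ER prolyl isomerase, 7.61-fold. Gm15344, a noncoding gene at 8.28-fold in the authors' deposited table, lies inside Hsp90b1 on the same strand, so its value is uncertain. Rbm15b, chosen after its value was seen, has 2 IDs under this name in the authors' deposited table, ENSMUSG00000074102 at 7.37-fold higher and ENSMUSG00000045365 at 4.33-fold. The first lies inside the annotated span of Manf on the same strand and is uncertain for the same reason, and the other has no match in GENCODE M21.

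**Figure D1:**
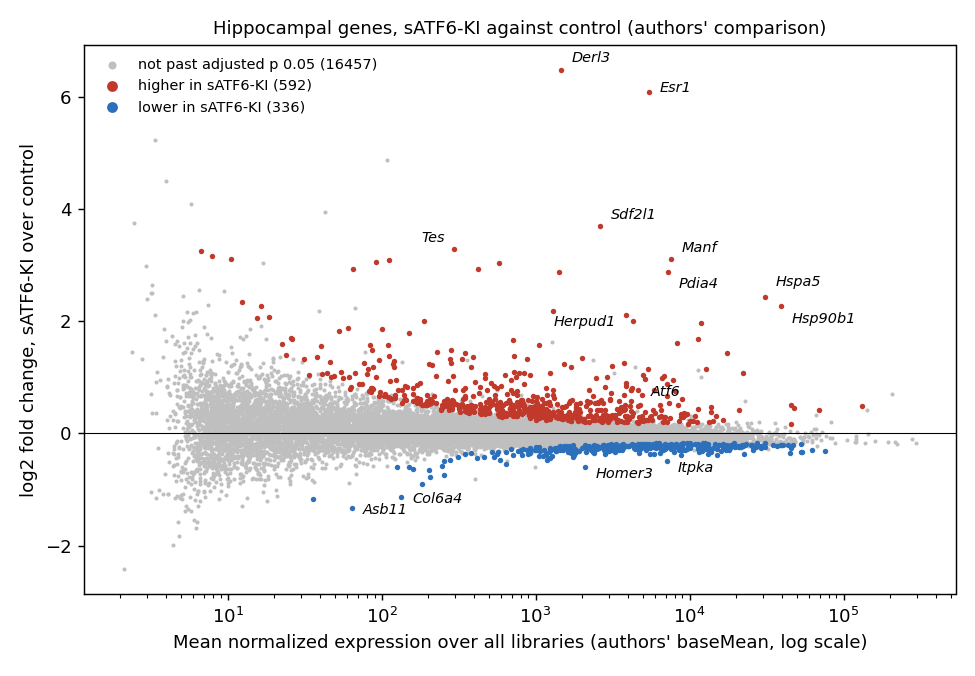
Log2 fold change of sATF6-KI over control against the authors' mean normalized expression on a log axis, 1 point per gene. Red points are the 592 genes higher and blue points the 336 genes lower at the authors' adjusted p under 0.05, and the red points reach further from 0 than the blue.

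The decreases were smaller. Asb11, a ubiquitin ligase subunit, fell by 1.34 ± 0.26 on the log2 scale in the authors' deposited table, and Col6a4, a collagen chain, fell by 1.14 ± 0.26. Alox12b, a lipoxygenase, was 1.88-fold lower in the authors' deposited table, Lefty1, a TGF-beta family antagonist, 1.71-fold and Prss35 1.67-fold. Gm129, named Ciart in GENCODE M21 and known as a circadian repressor, was 1.57-fold lower in the authors' deposited table, and Mc4r, the melanocortin receptor, was 1.55-fold lower. Homer3, a postsynaptic scaffold, Inhba, an activin subunit, and Syce2, a synaptonemal complex protein, were each 1.52-fold lower in the authors' deposited table.

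**Figure D2:**
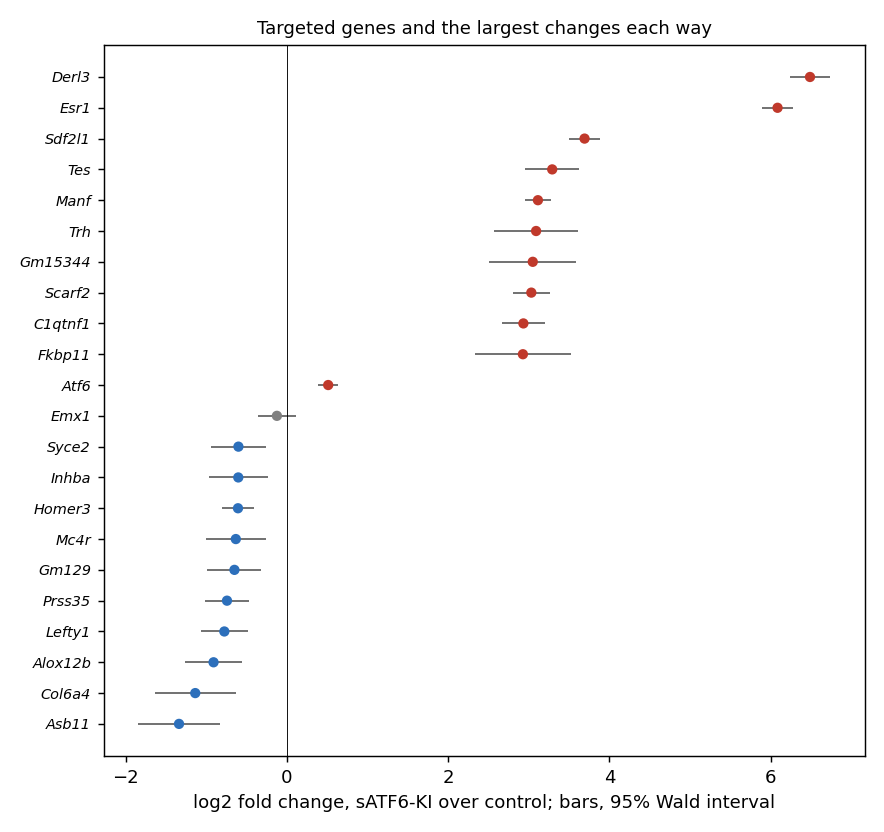
Log2 fold change of sATF6-KI over control in the authors' table for Atf6, Esr1, Emx1 and 10 genes each way. These 10 have the largest change each way among called genes with a baseMean of at least 1 after scaling. Bars are 95% Wald intervals. Red is higher, blue lower and grey not past the authors' adjusted p of 0.05. All but that of Emx1 exclude 0, which follows from the choice of called genes except for Atf6 and Esr1.

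ER chaperones and folding enzymes rose together. Of 21 measured members 19 were higher and none lower in the authors' deposited table, 20 higher when adjusted over the list alone, with a median log2 fold change of 1.15. Beside Sdf2l1 and Manf, Pdia4, a disulfide isomerase, was 7.36-fold higher in the authors' deposited table and Hsp90b1, the ER HSP90, 4.81-fold. Hspa5, the ER HSP70 known as BiP, chosen after its value was seen, was 5.41-fold higher in the authors' deposited table. The 2 members not past the threshold were Mesdc2, at 0.15 ± 0.08 on the log2 scale in the authors' deposited table, and Txndc5, at 0.07 ± 0.08. The cameraPR test of limma gave this list an adjusted p below the smallest number R can hold, and 5.87e-11 on ranks.

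Of 19 measured genes of ER-associated degradation 10 rose and none fell in the authors' deposited table, with 11 higher and 1 lower when adjusted over the list alone (cameraPR adjusted p = 8.76e-63, and 0.0024 on ranks). Beside Derl3, Herpud1 was 4.02-fold higher in the authors' deposited table, Sel1l, the partner of the ubiquitin ligase Hrd1, 2.70-fold and Os9, a lectin that picks misfolded glycoproteins, 1.94-fold. Among 20 N-glycosylation genes 7 rose and none fell in the authors' deposited table, 8 higher when adjusted over the list alone (cameraPR adjusted p = 3.28e-05, and 0.032 on ranks). They included Uggt1, the folding sensor of glycoproteins, at 1.66-fold in the authors' deposited table, and the oligosaccharyltransferase subunits Ddost at 1.49-fold, Rpn2 at 1.34-fold and Stt3b at 1.30-fold. Of 26 genes of ER translocation and early secretory transport 3 rose and none fell, 3 when adjusted over the list alone, among them Spcs3 at 1.42-fold in the authors' deposited table, Sec63 at 1.17-fold and Sec11a, a signal peptidase subunit, at 0.32 ± 0.08 on the log2 scale. That list had a median log2 fold change of -0.02 and a mean of 0.04, and its test did not pass (cameraPR adjusted p = 0.327, upward).

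Some genes of the lists for the other branches of the unfolded protein response rose as well. Whether those branches were themselves active was not tested. Of 22 measured in the PERK-ATF4 branch 3 rose and none fell in the authors' deposited table, and 6 rose when adjusted over the list alone. The 3 were Trib3, a pseudokinase, at 2.57-fold in the authors' deposited table, Ddit3, the transcription factor CHOP, at 2.52-fold, and Atf4 at 0.26 ± 0.07 on the log2 scale, while Chac1 was at 0.40 ± 0.14 (the authors' adjusted p = 0.059). Of 16 in the IRE1-XBP1 branch 4 rose and none fell, 4 when adjusted over the list alone, led by Gmppb at 1.80-fold and Xbp1 at 1.79-fold in the authors' deposited table. Edem1, which rose by 0.40 ± 0.08 on the log2 scale in the authors' deposited table, is also in the ER-associated degradation list. Sec24d, Sec61a1, Kdelr3, Sec23b, Ssr1 and Tram1 are also in the ER translocation list. The PERK-ATF4 and IRE1-XBP1 lists passed at cameraPR adjusted p = 0.00845 and 0.00413. The first lost its call at an inter-gene correlation of 0.05 (adjusted p = 0.0674), and the other on ranks (adjusted p = 0.158).

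Choroid plexus markers were higher in sATF6-KI in the same comparison as these ER gene groups. Of 12 measured, 11 rose in the authors' deposited table and all 12 did when adjusted over the list alone. Their median log2 fold change was 0.47 (cameraPR adjusted p = 3.35e-11, and 3.63e-06 at an inter-gene correlation of 0.1). Markers of the same tissue may move together, and this p does not measure how they vary between mice. Tmem72 was 2.10-fold higher in the authors' deposited table and Kl, the gene for klotho, 1.42-fold. Ttr, the transthyretin gene and one of the most abundant choroid plexus transcripts, chosen after its value was seen, was 1.41-fold higher in the authors' deposited table. Endothelial and mural cell markers did not pass as a list (cameraPR adjusted p = 0.0949): 1 of 14 rose, Pdgfrb at 1.19-fold in the authors' deposited table, and 2 rose when adjusted over the list alone, while Slco1a4 was at 0.20 ± 0.07 on the log2 scale. Among 13 thalamus and striatum markers 1 rose, 1 when adjusted over the list alone, namely Ppp1r1b at 1.26-fold in the authors' deposited table, while Ntng1 was at 0.16 ± 0.09 (cameraPR adjusted p = 0.235).

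Markers of glutamatergic forebrain neurons were lower. Of 14 measured 3 fell and none rose in the authors' deposited table, 4 fell when adjusted over the list alone, and the list had a median log2 fold change of -0.13 (cameraPR adjusted p = 0.00195). Choroid plexus markers, with a median of 0.47, moved the other way in the same comparison. Itpka, an inositol trisphosphate kinase of dendritic spines, fell by 0.49 ± 0.07 on the log2 scale in the authors' deposited table and Zbtb18, a transcriptional repressor, by 0.24 ± 0.06. Of 20 glutamatergic synapse genes 3 fell and 1 rose in the authors' deposited table, 5 and 2 when adjusted over the list alone (cameraPR adjusted p = 0.0318). Slc17a7 and Camk2a are in both this list and the neuron marker list, so the lists are not fully separate. Camk2b, a subunit of a synaptic kinase, was 1.26-fold lower in the authors' deposited table and Shank3, a postsynaptic scaffold, 1.17-fold lower. The synapse list lost its call at an inter-gene correlation of 0.05 (adjusted p = 0.12), and the neuron marker list at 0.1 (adjusted p = 0.062). No GABAergic interneuron marker of 14 was called by the authors' DESeq2 test, at an unadjusted p under 0.05 or when adjusted over the list alone, and Reln at 0.17 ± 0.09 and Cck at -0.12 ± 0.07 on the log2 scale were nearest in the authors' deposited table. That list had a median of 0.03 and a test that pointed downward (cameraPR adjusted p = 0.992).

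Among glial markers, 1 of 12 astrocyte genes fell, Aldoc at 1.19-fold lower in the authors' deposited table, and 4 fell when adjusted over the list alone, while Gfap was at -0.16 ± 0.06 on the log2 scale (cameraPR adjusted p = 0.101). Of 16 reactive astrocyte genes 2 rose and none fell, 2 and 1 when adjusted over the list alone: Cxcl10, a chemokine, was 2.64-fold higher in the authors' deposited table and H2-T23 1.36-fold (cameraPR adjusted p = 0.588). Of 14 microglia markers 1 fell, 1 when adjusted over the list alone, namely P2ry12 at 1.23-fold lower in the authors' deposited table (cameraPR adjusted p = 0.213). Oligodendrocyte markers passed as a list, downward, with a median log2 fold change of -0.13 (cameraPR adjusted p = 0.0343, and 0.117 at an inter-gene correlation of 0.05). None of these 14 was called by the authors' DESeq2 test or when adjusted over the list alone, and 4 were lower at an unadjusted p under 0.05, with Olig2 at -0.21 ± 0.08 and Opalin at -0.21 ± 0.10 nearest in the authors' deposited table. Here too the choroid plexus markers, with a median of 0.47, moved the other way in the same comparison.

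**Figure D3:**
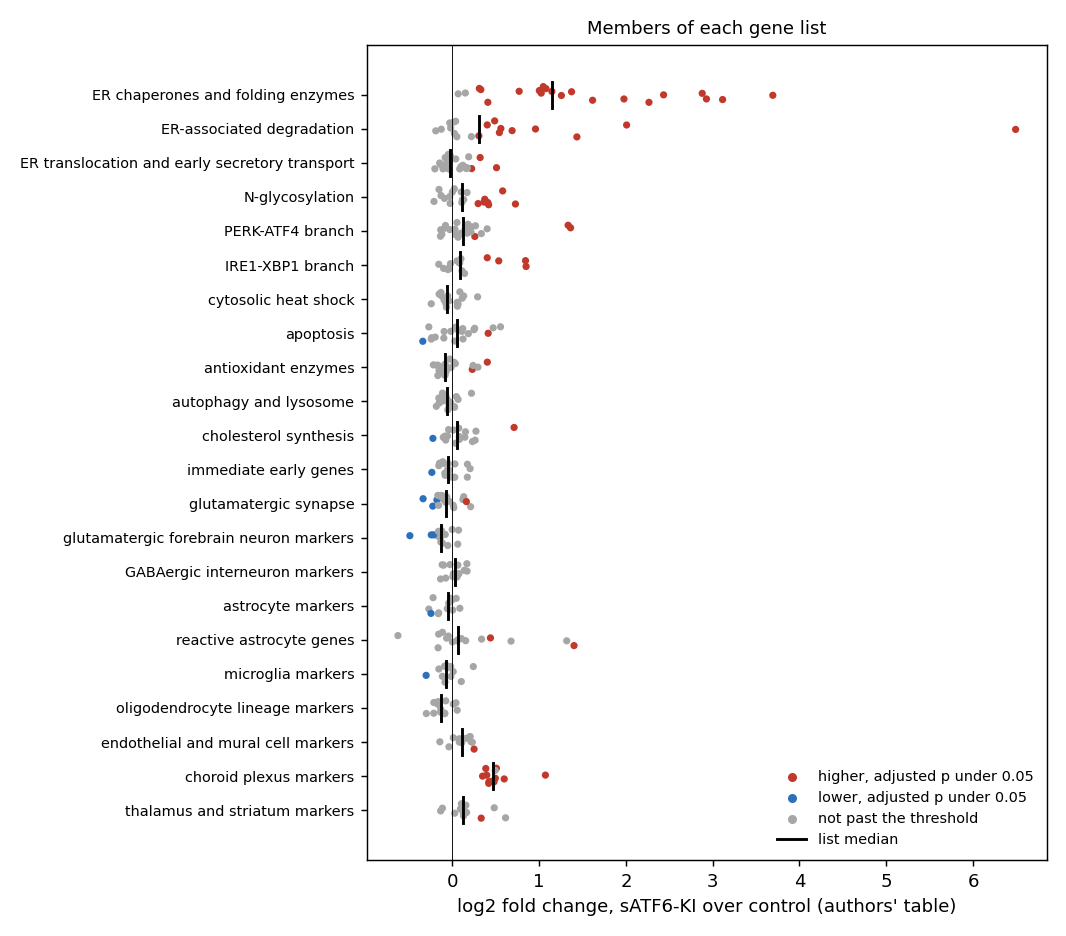
Log2 fold change of sATF6-KI over control in the authors' table for the members of each gene list, 1 point per gene, with the list median as a black bar. Red and blue points passed the authors' adjusted p of 0.05 upward and downward; ER chaperones have a median of 1.15 and choroid plexus markers one of 0.47.

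Other lists held few calls. Of 20 apoptosis genes 1 rose and 1 fell, 1 and 2 when adjusted over the list alone: Bcl2l11, the gene for Bim, was 1.33-fold higher in the authors' deposited table and Bok 1.27-fold lower (cameraPR adjusted p = 0.987). Of 21 antioxidant genes 2 rose and none fell, 2 and 3 when adjusted over the list alone: Gpx8, an ER peroxidase, was 1.32-fold higher in the authors' deposited table and Cat, catalase, 1.17-fold (cameraPR adjusted p = 0.261). Of 18 cholesterol synthesis genes 1 rose and 1 fell, 3 and 1 when adjusted over the list alone: Mvd was 1.64-fold higher in the authors' deposited table and Srebf2, a regulator of the pathway, 1.17-fold lower (cameraPR adjusted p = 0.396). Homer1 was the 1 of 18 immediate early genes that fell, also when adjusted over the list alone, at 1.18-fold lower in the authors' deposited table, while Nr4a2 was at 0.21 ± 0.10 on the log2 scale (cameraPR adjusted p = 0.327). The cytosolic heat shock list of 18 also holds Hspd1 and Hspe1, which are mitochondrial chaperones. None of its genes was called by the authors' DESeq2 test or when adjusted over the list alone. At an unadjusted p under 0.05, 1 was higher and 4 were lower. Hsp90aa1 was at -0.15 ± 0.06 and Hsp90ab1 at -0.13 ± 0.05 in the authors' deposited table (cameraPR adjusted p = 0.244). No autophagy and lysosome gene of 20 was called by the authors' DESeq2 test or when adjusted over the list alone, with 1 higher and 4 lower at an unadjusted p under 0.05. Dapk1 was at -0.18 ± 0.06 and Wipi1 at 0.22 ± 0.08 in the authors' deposited table (cameraPR adjusted p = 0.151). Neither the 5 blood genes (cameraPR adjusted p = 0.588) nor the 5 sex-linked genes held a call of the authors' DESeq2 test, at an unadjusted p under 0.05 or when adjusted over the list alone. Hbb-b2 was at -0.25 ± 0.39 and Alas2 at -0.13 ± 0.23 on the log2 scale in the authors' deposited table, and Eif2s3y was at 0.11 ± 0.07 and Ddx3y at -0.11 ± 0.07.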

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

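The alternative with a fold change of at least 1.5 was planned before the data were examined, and all others here were chosen after seeing the data. No paired analysis was possible because no column of values per library was given to a sample. Also not run, for the same reason, were other normalizations and filters on counts, edgeR, DESeq2 and limma fits of the samples, pseudocounts, fry, an estimated correlation, fits without single replicates and other splits of the samples. The planned use of the authors' adjusted p is the main result. The 928 called genes were 217 at a fold change of at least 1.5, 514 at an adjusted p threshold of 0.01 and 268 by Bonferroni. The 592 higher genes were 206, 379 and 234 under these settings, and the 336 lower genes were 11, 135 and 34, and 529 at a threshold of 0.1. These settings loosen or tighten the call by construction. The counts stayed within 1.5 times with a baseMean of at least 10 (946 genes) and with protein-coding genes alone (941).

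For gene lists, ranks of the statistics ended the IRE1-XBP1 call (adjusted p = 0.158) and added calls for autophagy and lysosome genes (0.032, lower), astrocyte markers (0.0464, lower) and endothelial and mural markers (0.00500, higher). An inter-gene correlation of 0.05 ended the calls of the PERK-ATF4 branch (adjusted p = 0.0674), the glutamatergic synapse (0.12) and oligodendrocyte markers (0.117). At 0.1 these had adjusted p = 0.196, 0.265 and 0.239, and the calls of the IRE1-XBP1 branch (0.102) and glutamatergic neuron markers (0.062) ended too. The cause was not tested for ranks, while a higher correlation widens the error by construction. A baseMean of at least 10 changed none of the 23 list calls, nor did a background without the ER and unfolded protein response lists change any of the 17 it was run on. Of 81 named genes, 22 lost their call by Bonferroni and 25 at a fold change of at least 1.5; the fold change itself is the same deposited value under every setting.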

Other observations

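The gene families here were chosen after seeing the data by their symbols, 18 in number, and tested with cameraPR as the lists were. The tests of Tmem72, of the chaperones and of the Rosa26 window without its own locus below were also chosen after the result was seen, as was the bootstrap interval of the neighbours' median. Collagen genes were higher: of 43 measured, 16 rose and 1 fell in the authors' deposited table, 40 were above 0, and the median log2 fold change was 0.45 (adjusted p = 1.60e-09, and 0.0125 at an inter-gene correlation of 0.1). The choroid plexus markers, with a median of 0.47, moved in the same direction, and Col8a1, at 0.61 ± 0.11 in the authors' deposited table, is also in the second choroid plexus list used below. Col4a3 and Col4a4, chains of basement membrane collagen, were at 0.82 ± 0.16 and 0.85 ± 0.18 on the log2 scale in the authors' deposited table, and Col6a4 was the member that fell. MHC genes had a median of 0.39 with 24 of 26 above 0 and 2 called (adjusted p = 0.0187, and 0.0886 at an inter-gene correlation of 0.05). Among 15 GABA-A receptor subunits 3 rose in the authors' deposited table, Gabrq with the authors' adjusted p = 0.000761, Gabra5 at 0.34 ± 0.07 and Gabra2 at 0.29 ± 0.09. The family did not pass (cameraPR adjusted p = 0.413). Of 85 potassium channel genes 3 rose and 8 fell (cameraPR adjusted p = 0.385), and none of 25 glutamate receptor genes was called (cameraPR adjusted p = 0.934). Calcium channel, sodium channel, COPI and COPII coat and histone genes did not pass as families either.

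Several families had most members below 0, by small amounts. A check of gene length and GC content, set out for the small decreases before the data for it were looked at, was not run. Of 79 cytosolic ribosomal proteins 66 were below 0 and 10 fell in the authors' deposited table, with a median of -0.16 (adjusted p = 6.49e-07, 0.00693 at an inter-gene correlation of 0.05 and 0.0917 at 0.1). Of 37 complex I subunits 35 were below 0 and 3 fell, with a median of -0.14 (adjusted p = 7.14e-06, 0.00635 at a correlation of 0.05 and 0.0739 at 0.1), so neither call held at 0.1. Proteasome subunits had 35 of 39 below 0 and no call of the authors' DESeq2 test (adjusted p = 0.00175, and 0.0606 at 0.05). Cytochrome oxidase subunits had 12 of 17 below 0 and 3 that fell (adjusted p = 0.0265, and 0.0886 at 0.05). Aminoacyl-tRNA synthetases did not pass (adjusted p = 0.127): 1 of 18 rose and none fell, and 15 were below 0. On ranks of the statistics they did pass, downward (adjusted p = 0.0133), and so did interferon-induced genes, upward (0.0136 on ranks, 0.257 on values). Vacuolar ATPase subunits had 16 of 21 below 0 and no call of the authors' DESeq2 test (adjusted p = 0.0187, and 0.0886 at 0.05). FK506-binding proteins passed upward on values (adjusted p = 0.0265) and not on ranks (0.824, downward), with a median of -0.05, 4 of 13 higher and 2 lower. Among the higher ones, Fkbp11 and Fkbp2 are also in the ER chaperone list, so the upward call is not separate from that list's. Tubulin genes went both ways: 5 of 14 fell, led by Tuba4a at -0.37 ± 0.06 in the authors' deposited table, and 2 rose, Tubb3 at 0.28 ± 0.08 and Tubb4b at 0.21 ± 0.06. As a family they passed downward (adjusted p = 0.014, and 0.0606 at 0.05).

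The rise of choroid plexus markers may come from more choroid plexus tissue in the sATF6-KI dissections. A second list of 21 choroid plexus genes, written down before its values were looked at and sharing no gene with the fixed lists, had all 21 above 0, 12 of them past the authors' adjusted p, and a median log2 fold change of 0.442, near the 0.47 of the markers. Added tissue is not argued against for the markers: Tmem72 lay 5.1 of its Wald standard errors above the median of the other 11 markers, 0.45, but it was picked as the highest of them. For the rise of the ER chaperones, a separate pattern, the 19 raised ones were set against the highest choroid plexus marker. Of these, 9 lay above it by more than 3 of their Wald standard errors. Added tissue would not raise a gene more than the tissue's own markers, so these values argue against it as the only cause for those 9. The comparison was set after both sets of values were seen, and it decides nothing for the other raised chaperones. Whether any extra tissue was in 1 library or in all, and whether sATF6 acts in choroid plexus cells, stays open.

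Genes next to a strongly raised gene could be higher because reads run past the end of that gene. Around 95 genes raised at least 2-fold, 49 same-strand genes within 20 kb downstream had a median log2 fold change of -0.0047 (bootstrap 95% interval -0.0328 to 0.0869), against 0.05 for 66 genes within 20 kb upstream. The one-sided permutation test of mean log2 fold change, downstream above upstream, gave p = 0.904 with 100000 permutations. The means were 0.062 downstream and 0.137 upstream, and 3 downstream and 9 upstream genes were called higher. Neighbours that were themselves called and raised at least 2-fold were left out, and upstream genes were taken from either strand. The test therefore cannot decide whether reading past the end raised the neighbours left out. For the downstream genes kept, a median near 0 goes against a common rise. Genes that overlap a raised gene, such as Rbm15b inside Manf and Gm15344 inside Hsp90b1, were outside this test, and shared reads stay open for them. No biological explanation was tested.

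Genes near the Rosa26 insertion could change through flanking DNA or a local effect. Within 5 Mb of Gt(ROSA)26Sor 7 of 87 genes passed the authors' adjusted p (8.05%), against 917 of 17079 elsewhere (5.37%), an odds ratio of 1.54 (Fisher's exact test, two-sided, p = 0.235). One of the 7 is Gt(ROSA)26Sor itself, without which 6 of 86 passed (6.98%, Fisher's exact p = 0.468). The 5 listed genes within 200 kb of the locus were not called by the authors' DESeq2 test, 0 of them at an unadjusted p under 0.05, with log2 fold changes from -0.17 ± 0.09 for Thumpd3 to 0.04 ± 0.07 for Setd5 in the authors' deposited table; these values go against a local rise of the size seen at Gt(ROSA)26Sor, 0.54. Over the wider window a local effect cannot be told apart from none with so few genes. The 7 include Tmem72, 3.60 Mb from the locus, and Edem1, an ER-associated degradation gene, so the genotype effect on such genes stays open as well.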
